A study of Homo sapiens with 4 samples.

How the data were processed

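mRNA libraries were made, per the labels' protocols, from RNA isolated with RNeasy Mini columns, with 1 µg of total RNA and the Universal Plus mRNA-Seq kit, from SW1736 and 8505C cells given vehicle or 1.5 µM DHT for 24 h. Per the submitters' processing notes, bcl2fastq 2.20 and StringTie were used with the hg38 build. The aligner, the annotation and the version of StringTie are not given in the sources used here. The files deposited by the authors are gene abundance tables with a TPM, an FPKM and a mean coverage per gene and locus, per the file headers. TPM as deposited by the authors sums to 1000000 in each library, which fixes the mean and passes a gain of abundant mRNAs on to all others as a loss. FPKM as deposited is scaled by mapped fragments and by length, and coverage as deposited is the mean read depth over a gene's exons, without scaling by library.

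Rows of one gene identifier, such as copies on alternate haplotypes, were summed (1446 identifiers had several rows in a file). Of 26485 identifiers, 25400 were matched to a current gene: 23758 by RefSeq symbol, 869 through the GENCODE 29 gene of that name and 773 by a synonym naming 1 gene. The others held 0.556% of TPM. Of the matched genes 19085 were protein-coding, and 11723 of these had a mean of at least 1 TPM over the 4 libraries. Folds were differences of log2(TPM + 1). Mitochondrially encoded genes have no entry in the tables and were left out. Values of a few genes and of 1 list are not reported here.

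With 1 library per group, the comparisons within a line and between untreated lines are counts of genes at least 2-fold apart, without a test. Fixed before the data were examined were 39 gene lists, 35 of which had 5 or more measured members. The median fold of each was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and stood apart under the percentile 2.5 or over 97.5. Also fixed were the genes to name: those 2-fold in the same direction in both lines (12 each way at most) and the 5 highest and 5 lowest of each line whose fold in the other line was small or opposite, all at a mean of 5 TPM or more, a panel of 37 genes, up to 4 members of each list with the largest mean fold, and for the untreated lines the 8 highest and 8 lowest at a mean of 20 TPM or more with the thyroid genes. Other names are marked as chosen afterwards.

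Treatment over both lines was fitted with limma 3.58.1 in R 4.3.3 (trend, empirical Bayes, two-sided, Benjamini-Hochberg over all genes), with 1 residual degree of freedom. All else was computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The fit was tested on simulated data for 11723 genes, with noise set by the disagreement of the lines. Of 50 genes changed in both lines at each size, it called 30% at 1.5-fold, 80% at 2-fold and 100% at 4-fold, and 0.0434% of unchanged genes. Of genes changed in SW1736 alone it called 0%, with finite prior degrees of freedom, so the simulation does not show the behaviour met in the data. In 20 simulated lists of 30 genes, a shift of 0.5 was found in 20 and an unshifted list stood apart in 0.

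The alternatives were other pseudocounts, filters and thresholds, median scaling, scaling without ribosomal protein and non-coding genes, FPKM, all annotated genes, unmatched random lists, list means and other limma settings. Coverage, single-locus genes and the removal of trends on mRNA length, GC content and expression (from GENCODE 29 transcripts, for 11699 genes) were added after the data were seen. Removing the trends also centres the folds of each line on their mean.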

Results

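RNA was sequenced from 2 cell lines derived from anaplastic thyroid cancer, SW1736 and 8505C, after 24 h with vehicle (DMSO) or with 1.5 µM DHT, which stands for dihydrotanshinone in this series, a tanshinone of Salvia root and not the androgen of the same abbreviation. Each line and treatment was represented by 1 library, 4 in all, so no difference within a line has a replicate check. Expression was taken as the deposited TPM, a length-scaled share of all transcripts, for 26485 gene identifiers, and 11723 protein-coding genes with a mean of at least 1 TPM were compared on the log2(TPM + 1) scale, which understates the fold of low genes. The ratio of coverage to FPKM gave depths of 3.67 and 3.85 Gb of aligned bases for SW1736 with DMSO and DHT, and of 3.27 and 4.15 Gb for 8505C. Read numbers are unknown, so no counting interval is given. Coordinates are those of the deposited tables (hg38).

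The untreated lines were compared first, as the background to the treatment. They differed in thyroid transcription factors: PAX8 stood at 87.1 TPM in SW1736 and 0.282 in 8505C, FOXE1 at 60.6 and 0.101, whereas NKX2-1 was listed at 0 in SW1736 and at 69.8 in 8505C. TG and TSHR, which encode thyroglobulin and the thyrotropin receptor, were listed at 0 in both DMSO libraries. 8505C carried high MMP1 (6015 TPM, an interstitial collagenase), CD24 (859), KISS1 (837) and ESM1 (503), and SW1736 carried MT1E (932), COL1A1 (349.9) and CD70 (463). MMP1 and ESM1 were listed at 0 in SW1736 and MT1E in 8505C, so no fold is given for them. In all, 1169 genes were at least 2-fold higher and 1481 at least 2-fold lower in 8505C than in SW1736.

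Markers of other cell types were read first as levels. Of 20 immune markers 2 reached a mean of 1 TPM, CD68 and CD14, and of 17 markers of common contaminating lines none did. Of 13 endothelial markers 5 did, all of them higher in 8505C, with CDH5 at 128 TPM and TIE1 at 43.4 in its DMSO library and both listed at 0 in SW1736, whereas EGFL7 was at 67.8 and 8.29. Of 16 melanocyte and neural markers 4 did, the highest being TUBB3. Of the epithelial genes, KRT7, KRT8 and KRT18 were abundant in both lines, whereas CDH1 was at 0.0631 TPM in SW1736 and 0.0247 in 8505C.

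With DHT, the first question was how the mRNAs of each line differed from those given vehicle. In SW1736, most immediate early mRNAs and some heat shock, hypoxia and cytokine mRNAs were far higher with DHT, and some cell cycle and DNA repair mRNAs were lower. EGR1, an immediate early transcription factor (chromosome 5, 138465492 to 138469315), stood at 2.62 TPM with DMSO and 2060 with DHT, a log2 fold of 9.15. The heat shock gene HSPA6 (chromosome 1, 161524540 to 161526897) had a log2 fold of 7.47, FOS of 7.11, the hypoxia-responsive peptide gene ADM of 6.48, GEM of 5.69 and BHLHE40 of 5.66. RPSAP58, a copy of the ribosomal gene RPSA, was lowest (-6.98) and was low in 8505C too. The lowest genes of SW1736 that were not so in 8505C, at a mean of 5 TPM or more, were HYLS1 (log2 fold -2.90), ETAA1 (-2.82), PRSS23 (-2.68), the mitotic spindle gene ASPM (-2.65) and TUBB, a beta tubulin (-2.63, from 1835 to 295 TPM, with further copies on alternate haplotypes). In 8505C the genes of this paragraph other than RPSAP58 lay between -0.41 for EGR1 and 0.66 for TUBB, and the difference between the lines was not tested.

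Across the 11723 genes, 326 were at least 2-fold higher and 1826 at least 2-fold lower with DHT in SW1736. Most genes shared a displacement: the median log2 fold of genes with a mean of at least 5 TPM was -0.43, beside -0.03 in 8505C. Centred on that median, which by construction evens the split, 560 genes were 2-fold higher and 477 lower. With FPKM in place of TPM the split was 318 higher and 696 lower, and with ribosomal protein and non-coding genes left out of the scaling it was 386 and 1555. Gene groups are therefore set beside random lists of the same size and matched expression, which carry the displacement of genes at that expression. The displacement also varied with mRNA length and GC content, on which these lists are not matched.

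**Figure D1:**
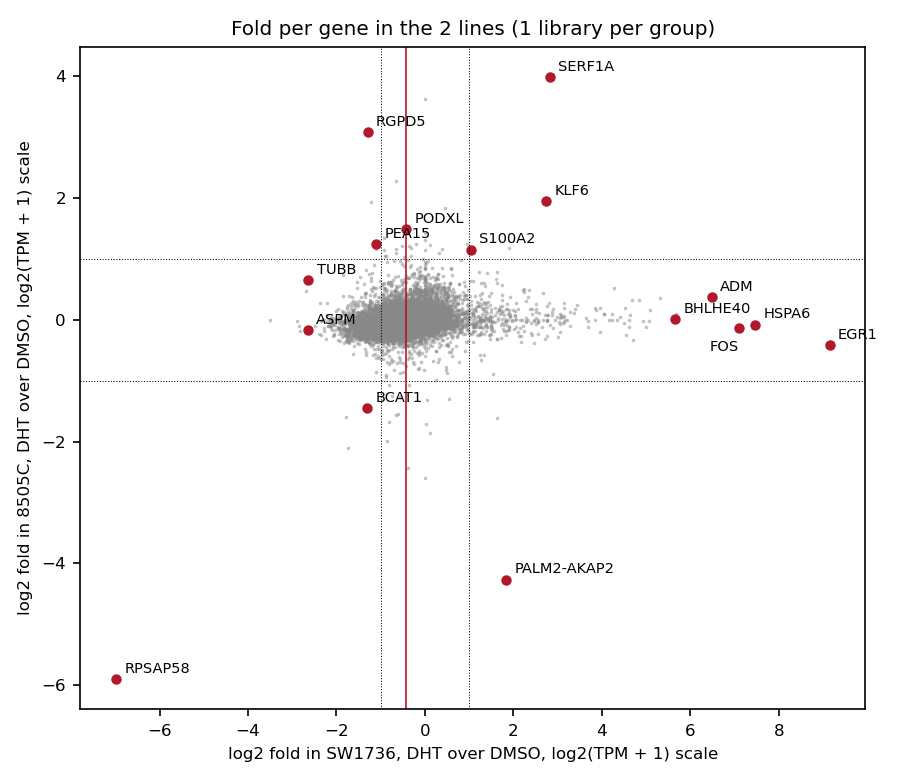
Log2 fold with DHT over DMSO in SW1736 (x axis) and 8505C (y axis) for each of 11723 genes, on the log2(TPM + 1) scale, with 1 library per group. Dotted lines mark 2-fold and the red line the median SW1736 fold of -0.42; EGR1 lies at 9.15 in SW1736 and at -0.41 in 8505C.

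Immediate early genes, the first to be transcribed after a stimulus, stood farthest from the random lists. Of 33 measured members, 23 were at least 2-fold higher in SW1736 and 1, MCL1, was 2-fold lower (-1.47). MCL1 has several loci or overlaps another gene, so its value is less certain. The same holds for CDKN1A, DDIT3, TXNRD1, TNFAIP3, VEGFA, FKBP5, ESM1 and EGFL7 among the genes named here. The median log2 fold of the 33 immediate early members was 2.42, beside -0.36 for matched random lists (percentile 100 of 10000 lists). FOSB (5.01), NR4A1 (4.92), ATF3 (4.71) and DUSP1 (3.29) were among them, and MYC went from 125 to 614 TPM. In the heat shock list 9 of 27 members were at least 2-fold higher and none lower, with a median of 0.12 (percentile 99.3). These were inducible chaperones such as HSPA1A (4.04), HSPA1B (4.05) and the small heat shock protein gene CRYAB (5.32). HSPA1A and HSPA1B are near-identical and share reads, so their separate values are uncertain.

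Hypoxia and glycolysis genes (median 0.37, percentile 100) had 14 of 33 members 2-fold higher and none lower, among them NDRG1 (4.24), the glucose transporter gene SLC2A3 (3.96) and HK2 (2.71), which encodes a hexokinase. Of 27 NF-kB and cytokine genes, 12 were 2-fold higher and none lower (median 0.77, percentile 100), with CXCL8 at 2.32 and 62.9 TPM, CSF2 at 1.41 and 47.9, and TNFAIP3 at 2.11 and 38.7. CXCL3 was listed at 0 with DMSO and at 27.8 TPM with DHT. TGF-beta targets (median 0.40, percentile 100) had 6 of 18 members higher and 2 lower, with SNAI2 at 2.88 and SMAD7 at 2.82. Replication-dependent histones had 16 of 32 higher and none lower (median 0.93, percentile 100), led by HIST1H2BG at 2.17 and 77.5 TPM. Histones are a multigene family whose mRNAs largely lack poly(A) tails, so both their capture and their read assignment are uncertain. Senescence secretory genes (median 0.29, percentile 100) had 4 of 20 members higher and 1 lower. The 4 were CXCL8, CXCL2 (2.28), CXCL1 (1.34) and CDKN1A (2.76), and the NF-kB list also holds CXCL8. Centred on the median gene, the members 2-fold higher were 21 for histones, 16 for NF-kB genes, 15 for hypoxia genes, 7 for TGF-beta targets and 7 for the senescence list, with none lower in these lists, and the counts of the immediate early and heat shock lists were as above.

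Stress responses were uneven within their lists. In the ATF4 list, 7 of 38 members were 2-fold higher and 2 lower, and the median of -0.20 lay inside the range of random lists (percentile 93.3), though the list stood apart by the mean and beside random lists without matching. CEBPB (5.09), DDIT4 (5.07), PPP1R15A (3.86) and DDIT3 (2.90) were high, whereas ASNS was at -0.17. The list of NRF2 targets did not stand apart (percentile 95.6), but did so beside lists matched on mRNA length (98.8) or without matching, with single-locus genes, and with ribosomal protein and non-coding genes left out of the scaling. Its heme oxygenase gene HMOX1 stood at 4.41 while TXNRD1 was at -1.36, SLC7A11 at -1.62 and NQO1 at -0.10. Of 30 genes of the unfolded protein response of the endoplasmic reticulum, 2 were higher, among them the chaperone gene HSPA5 (1.79), and 2 lower. Centred on the median gene, 4 were higher and none lower. The median of -0.13 lay inside the range of random lists (percentile 92.8). The list did stand apart beside lists matched on mRNA length (98.25) or without matching. CDKN1A, which encodes an inhibitor of cyclin-dependent kinases, was at 2.76.

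Proliferation and repair genes lay below the random lists in SW1736, while their counts at 2-fold depended on the centring. Of 42 genes for crosslink and excision repair, 19 were at least 2-fold lower, or 6 centred on the median gene, and none higher (median -0.96 beside -0.51 for random lists, percentile 0), with XRCC2 at -2.15, FANCM at -1.87, BRCA1 at -1.72 and BRCA2 at -1.67. ERCC1, which encodes a subunit of an excision endonuclease, was at 0.17. The lists for G1/S (11 of 40 lower, median -0.74), G2/M (11 of 38, -0.70) and the spindle checkpoint (6 of 21, -0.87) had no member 2-fold higher. Centred on the median gene, 4, 6 and 1 members of these lists were lower, and 1 spindle checkpoint gene was higher. MKI67 went from 250 to 76.6 TPM and CENPF from 92.4 to 19.5, whereas MAD2L1 was at -0.50 and CCNB1 at -0.36. YAP/TEAD targets had 7 of 22 members lower, and 0 when centred (median -0.76), including CRIM1 (-1.40), but GADD45B (4.51) and ANKRD1 (4.62) were far higher, and by the mean the list lay 0.10 above random lists. Ribosomal proteins were 0.38 higher in the median, with 74 of 75 members above 0 and none at 2-fold (1 when centred), and they held 16.5% of TPM with DMSO and 21.6% with DHT.

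**Figure D2:**
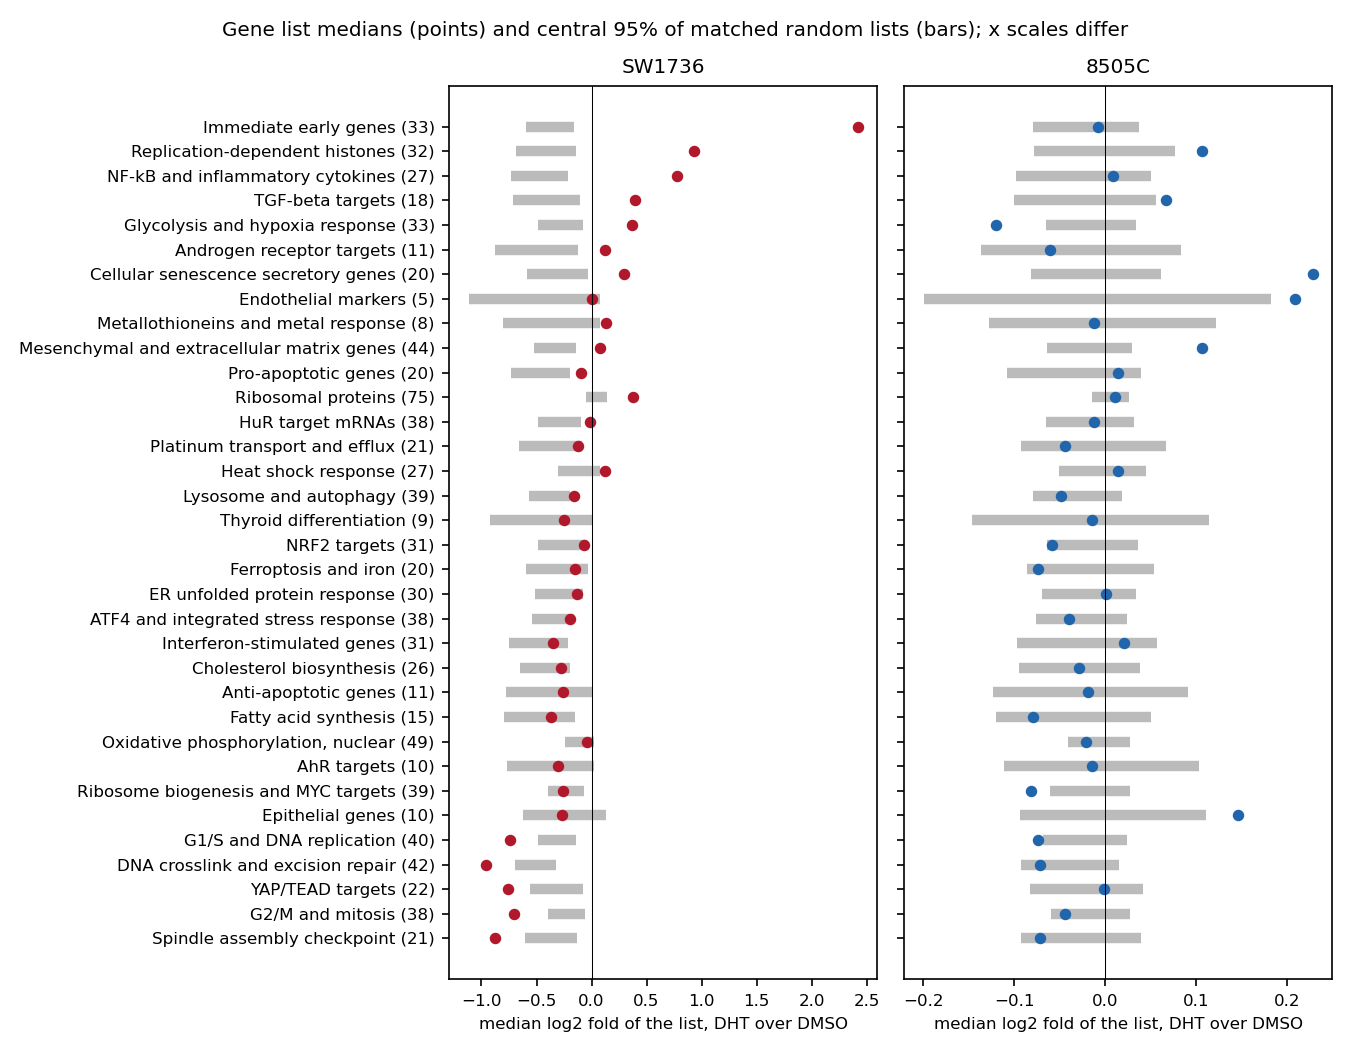
Median log2 fold with DHT over DMSO of each gene list reported (points, number of measured members in brackets) in SW1736 and 8505C, with bars for the central 95% of 10000 random lists matched on expression. The x scales differ: immediate early genes reach 2.42 in SW1736 and -0.01 in 8505C.

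In 8505C, few mRNAs differed at this dose and time. The early response gene KLF6, a zinc finger transcription factor (chromosome 10, 3775996 to 3785281), went from 14.2 to 57.9 TPM (log2 fold 1.95), the podocalyxin gene PODXL from 43.8 to 125 (1.49), NKX2-1 from 69.8 to 174 (1.31) and PEA15 from 182 to 435 (1.249). BCAT1, a cytosolic branched-chain aminotransferase, went from 37.2 to 13.02 (-1.45). Altogether 32 genes were at least 2-fold higher and 20 lower. Of these 52, 28 overlapped another gene, carried a read-through name or had several loci (53.8%, beside 17.1% of all genes tested), and their values are uncertain because reads can be shared. RGPD5, FAM156B, PALM2-AKAP2, INO80B and RBM12 were among them.

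Immediate early genes, with a median of -0.01, and NF-kB genes, with 0.01, lay within the range of random lists in 8505C, although both lists stood apart by the mean. EGR1 was at 18.3 TPM with DMSO and 13.5 with DHT, HSPA6 at 0.307 and 0.239, HMOX1 at 12.9 and 13.4, and CDKN1A at 29.7 and 29.6. KLF6 and DUSP4 (1.10, chosen after its values were seen) were the only immediate early genes at 2-fold. Of 35 lists 9 stood apart from random lists in 8505C, by small amounts. Above them, as in SW1736, were histones (0.11, percentile 99.4), TGF-beta targets (0.07, percentile 98.7), senescence secretory genes (0.23, percentile 100) and mesenchymal and matrix genes (0.11, percentile 100), including CXCL8 (0.52) and VIM (0.33). In SW1736 the mesenchymal and matrix list had a median of 0.08, beside -0.33 for random lists. Of its 44 members 3 were 2-fold higher there and 7 lower, or 3 and 1 centred on the median gene. Epithelial genes (0.15, percentile 99.1) and endothelial markers (0.21, percentile 98.5) were above random lists in 8505C too. Among the 5 endothelial markers, CDH5, TIE1 and FLT1 were listed at 0 in both SW1736 libraries, so that list is not compared between the lines. Below them were G1/S genes (-0.07, percentile 1.32), as in SW1736, and ribosome biogenesis genes (-0.08, percentile 0.14). Hypoxia and glycolysis genes were slightly lower by the median (-0.12, percentile 0), without any member at 2-fold, and did not stand apart by the mean. The folds of 8505C followed the GC content of the mRNAs (Spearman's rho 0.48 across genes, which are not independent replicates), and those of SW1736 did so less closely (0.31). Histones and TGF-beta targets did not stand apart in 8505C by the mean or among single-locus genes. G1/S genes did not by the mean, with coverage or beside random lists without matching, and ribosome biogenesis genes did not without matching. Epithelial genes did not with a pseudocount of 5, nor did TGF-beta targets, and epithelial genes did not without a filter on low values. Endothelial markers did not with a pseudocount of 0.1 or with all annotated genes. They were also not among the lists apart at a mean of 5 TPM, with coverage or with single-locus genes, where fewer members can remain. With trends on mRNA length, GC content and expression removed, 5 of the 9 lists stayed apart, without the TGF-beta, G1/S, epithelial and endothelial lists.

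The responses of the 2 lines were then set side by side. At least 2-fold in the same direction in both were 4 higher and 4 lower genes, where independent lists would share 0.890 and 3.12. The higher genes were KLF6 (2.74 in SW1736 and 1.95 in 8505C), S100A2 (1.04 and 1.15), SERF1A (2.83 and 3.99) and, chosen after its values were seen, PRH1 (1.90 and 1.18). The lower genes were BCAT1 (-1.31 and -1.45), RAB43 (-1.78 and -1.60), RPSAP58 (-6.98 and -5.90) and, likewise chosen afterwards, CNTF (2.32 and 3.31 TPM with DMSO and listed at 0 with DHT in both lines). SERF1A has a near-identical copy, RPSAP58 is a copy of the ribosomal gene RPSA, and RAB43, PRH1 and CNTF overlap other genes or have several loci. KLF6, S100A2 and BCAT1 were the shared genes without such a mark, though similar sequences elsewhere were not searched for. Relative to the median gene, BCAT1 was at -0.89 in SW1736, short of 2-fold. Across genes the folds of the lines correlated weakly (Pearson's r = 0.20, Spearman's rho = 0.30, without a p-value), and r was 0.11 once trends on mRNA length, GC content and expression were removed.

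**Figure D3:**
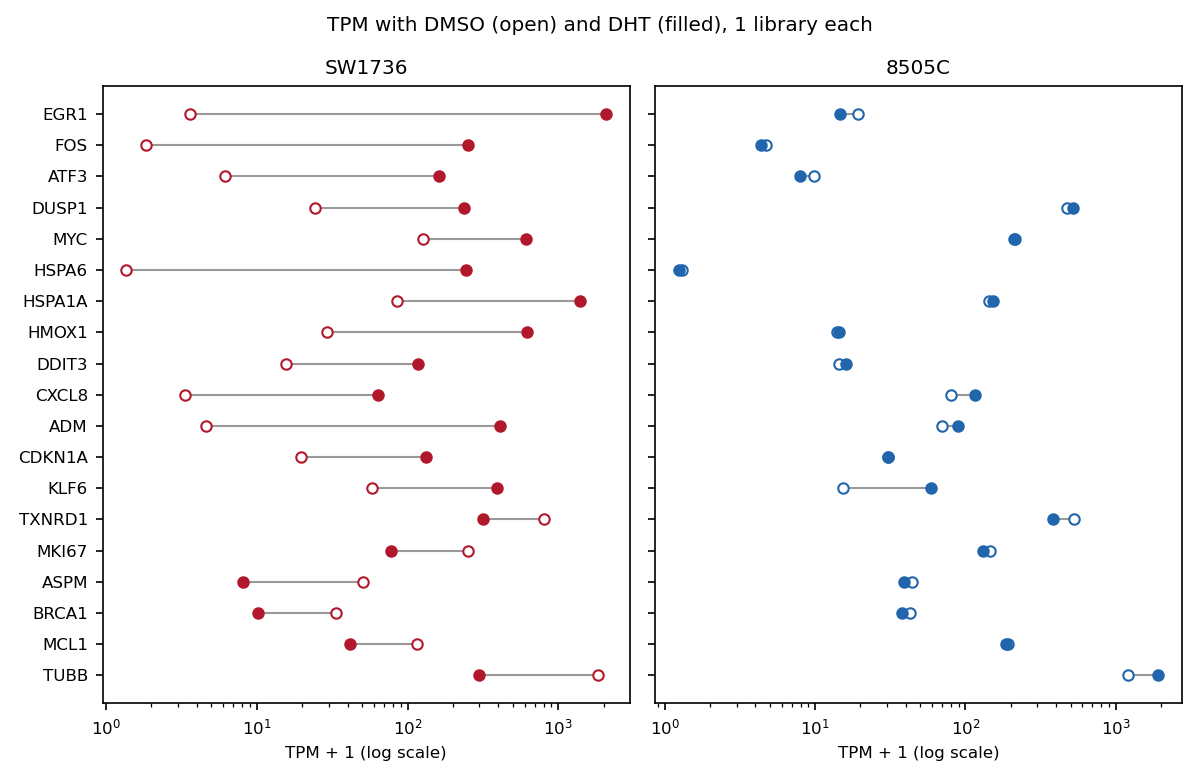
TPM + 1 (log axis) of 19 named genes with DMSO (open points) and DHT (filled points) in SW1736 and 8505C, 1 library each. EGR1 goes from 2.62 to 2060 TPM in SW1736 and from 18.3 to 13.5 in 8505C, while KLF6 is higher with DHT in both lines.

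A limma fit with the cell line as a block and the lines as replicates gave 97 genes higher and 26 lower past an adjusted p of 0.05. It was meant to ask for a like response in both lines and did not do so: the estimated prior degrees of freedom were infinite, so the difference between the lines did not enter a gene's own error. Of the 123 genes, 92 were within 1.2-fold in 8505C, 76 had one direction in both lines and 6 were 2-fold in both. EGR1 was called with an adjusted p of 9.4e-34 in this limma fit although its 8505C value was lower with DHT. The count was 2 with median scaling (RPSAP58 and SERF1A) and 3 without the mean-variance trend (those and KLF6), so the calls are not read as a response shared by the lines. Of the immediate early list, 16 members were called over all genes and 24 adjusted over the list alone, on the same footing. The counts were 7 and 9 for the heat shock list, 5 and 7 for NF-kB genes, 4 and 7 for hypoxia genes, 4 and 7 for histones, 6 and 6 for the ATF4 list, and 0 and 0 for crosslink repair.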

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

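The tests of scaling, depth, a wrong label, shared reads and trend removal were chosen after the result was seen. With 1 library per group, none of the differences between lines below was tested. The lines moved in opposite directions, at least 2-fold each way, for 6 genes, beside 8 in the same direction. With median scaling these counts were 2 and 9. Those among the genes chosen for naming were RGPD5, PEA15 (log2 fold 1.249 in 8505C and -1.10 in SW1736), FAM156B (1.93 and -1.21) and PALM2-AKAP2 (-4.27 and 1.83). RGPD5 moved by 3.09 on the log2(TPM + 1) scale in 8505C, where it was listed at 0 with DMSO and at 7.49 TPM with DHT, so that this is no fold, and by -1.30 in SW1736. Relative to the median gene of SW1736, RGPD5 was at -0.88, PEA15 at -0.68 and FAM156B at -0.80, all short of 2-fold. PALM2-AKAP2 was at 2.25. Hypoxia and glycolysis genes lay below matched random lists by -0.10 in 8505C and above them by 0.63 in SW1736, and the 8505C value was -0.07 once trends on mRNA length, GC content and expression were removed.

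Most genes had lower TPM in SW1736 with DHT. With ribosomal protein and non-coding genes left out of the scaling the median log2 fold was -0.34. That opposes scaling by these as the whole cause, and scaling by other mRNAs stays open without a spike-in. The summed FPKM of SW1736 was 438583 with DMSO and 511866 with DHT, beside 437144 and 444082 in 8505C. TPM divides by this sum, so part of the lower TPM of SW1736 is absent in FPKM. A loss of long mRNAs from the library stays open. The R2 of the fold on mRNA length was 0.0475, but R2 measures the spread between genes and not the shift of the median, so it cannot decide. In equal groups of genes by mRNA length, the median log2 fold of SW1736 was -0.25 in the shortest, -0.38 in the middle and -0.65 in the longest group. The genes with the shortest mRNAs were thus lower too, though less so. Trends on length (Spearman's rho -0.27) and on GC content (0.31) were present. Lower transcription of long genes remains open: at fixed mRNA length the rank correlation of fold and genomic span ran from -0.41 in the shortest bin to -0.0693 in the longest, and a like trend (-0.30 to -0.12) was present in 8505C without such a shift. An effect of DHT on SW1736 is untested without a second library.

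The response in 8505C was small. Depth is opposed as a cause, since the summed depth of its libraries was 0.986 times that of SW1736. A weaker form of the SW1736 response is opposed above a small size, and one under it stays open: genes 2-fold higher in SW1736 lay 0.0328 above matched random lists in 8505C and those 2-fold lower -0.06 from them, both outside the random range but under the bound of 0.1 set beforehand. A mislabelled or unexposed 8505C library cannot be told apart from a line that did not respond, because 1 library has no partner to check it. Only 8 genes were 2-fold in the same direction in both lines.

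Genes that overlap another, carry a read-through name or have several loci were 3.16 times as frequent among the 2-fold differences of 8505C as among all genes tested. Reads or isoforms assigned differently between such genes may therefore account for part of those differences, including RGPD5, FAM156B and PALM2-AKAP2. PEA15 is not among such genes. Similar sequences elsewhere were not searched for, so shared reads are not excluded for it. In SW1736 the share was 17.6%, beside 17.1% of all genes. No biological explanation was tested for this pattern.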

How the results depend on the processing

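The alternatives on coverage, single-locus genes and trend removal were added after the data were seen. Counts depended on the settings. In SW1736 2152 genes were 2-fold apart, and 915 with a pseudocount of 5, 1037 with median scaling, 1014 with FPKM and 889 with trends removed. Trend removal also centres the folds at a mean of 0, so the 889 belongs beside the 1037 of median scaling. The trends themselves had an R2 of 0.0996 in SW1736. In 8505C the 52 became 127 and 26 with pseudocounts of 0.1 and 5, 33 at a mean of 5 TPM, 117 with all annotated genes and 24 with single-locus genes. The 8 shared genes became 25, 5, 25 and 4 with pseudocounts of 0.1 and 5, all annotated genes and single-locus genes. Between untreated lines 2650 became 1602 with a pseudocount of 5. Thresholds of 1.5-fold and 3-fold gave 5033 and 440 genes in SW1736, 212 and 18 in 8505C, 47 and 5 shared, and 5051 and 1367 between lines. The 123 limma calls became 212 without a filter, 2 with median scaling, 4 without ribosomal protein and non-coding genes, 3 with FPKM, 3 without a trend, 28 with a robust prior and 0 without the cell line block, where 12 genes had an unadjusted p under 0.05. Without the block the difference between the lines enters the residual error, and the median standard error was 0.530, beside 0.383 with it. Residual and prior degrees of freedom together, capped at the gene number, were 11723 in the main fit. They were 8.04 to 20.5 in the settings with 2 to 4 calls. The robust fit also had 11723 with 28 calls, and the fit without a filter had 75.1 with 212. The cause of these other changes in the count was not tested. The correlation between lines was 0.11 with trends removed and within 1.5 times of 0.20 elsewhere. Lists standing apart numbered 20 in SW1736 and 9 in 8505C, and 19 to 24 and 6 to 10 over the alternatives. In SW1736 18 of the 20 stayed apart with trends removed, in 8505C 5 of the 9. YAP/TEAD targets lay 0.10 above random lists by the mean, against -0.45 by the median, since GADD45B and ANKRD1 weigh on a mean. No other list that stood apart and no named gene at 2-fold changed sign under the alternatives that gave it a value; ribosomal proteins have none where they were left out. Leaving out a line leaves 1 library per treatment and no residual degrees of freedom, so the values of the single lines stand in its place. Read numbers are unknown, which leaves counting error unmeasured.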

Other observations

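The tests on zinc finger and tubulin genes were set before their results were seen, and the comparisons matched on mRNA length and with trends removed were added afterwards. Other groups in SW1736 lay above random lists while their medians were near 0: HuR target mRNAs (median -0.01, 10 of 38 members 2-fold higher and 2 lower, percentile 99.9), pro-apoptotic genes (-0.10, percentile 99.7) and lysosome and autophagy genes (-0.16, percentile 99.3). Other lists also hold some of the higher HuR targets, so that list is not a separate result. Among these were FOS (immediate early list), CXCL8 (NF-kB), VEGFA (hypoxia) and HMOX1 (NRF2). Pro-apoptotic genes no longer stood apart with trends on mRNA length, GC content and expression removed, nor did lysosome genes by the mean or beside lists matched on mRNA length (percentile 97.0). ELAVL1, which encodes HuR, was at 73.5 TPM with DMSO and 56.2 with DHT. Androgen receptor targets also lay above random lists (median 0.12 beside -0.49, percentile 99.9), although of 11 members 1 was 2-fold higher, NDRG1, which the hypoxia list also holds, and 1 lower, FKBP5 (-1.21). Centred on the median gene, 1 member was higher and none lower, with FKBP5 at -0.79.

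A hypothesis was that mRNAs of zinc finger (ZNF) genes were lower as a class in SW1736 with DHT. The 411 measured genes had a median of -0.90, beside -0.48 for matched random lists (percentile 0), with 169 at least 2-fold lower and 6 higher. With random lists matched on mRNA length and expression the percentile was 0 as well, while GC content was not matched. In 8505C the median was -0.06 beside -0.01, at percentile 0 as well, and 0.01 with lists matched on mRNA length. The values are consistent with a lower class, as a hypothesis from 1 library per group, and say nothing of its cause.

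A second hypothesis held that alpha and beta tubulin mRNAs were lower together, as TUBB was. The 9 other tubulins had a median of -0.48 in SW1736, at percentile 4.30 of matched random lists, which did not reach the bound of 2.5, and TUBA1A, chosen after its values were seen, was at 1.27. TUBB2B, 1 of the 9, was listed at 0 in both SW1736 libraries. The data thus do not show a shared decrease. TUBB reads lay on its primary locus, and its copies on alternate haplotypes were listed at 0.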
